A study of Mus musculus with 4 samples.

How the data were processed

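RNA of mouse embryonic stem cells was sequenced from the parental line E14Tg2a and from lines without Dnm1l, Fis1 or Mff, 1 library per line, and samples were placed in these 4 groups by their genotype labels. The labels' protocols state that RNA was isolated with Trizol and that libraries were made with Illumina TruSeq kits. The design text of the series names the stranded version of the kit and the extraction label does not, and whether strand was used in quantification is not given in the sources used here. The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the fragments of the library), with 33818 RefSeq transcripts and 1 column per library, per the file headers. FastQC 0.11.5, STAR 2.5.2b, StringTie 1.3.3b, R 3.6.1 and the genome build mm10 are named, without role or order, per the submitters' processing notes. FPKM scales each library by its own total of fragments, so a few abundant transcripts can shift all others, and it does not sum to a common total across libraries. Per the file headers, the deposited table also holds transcript lengths in bases and positions. Starts were 1 below those of RefSeq in 18332 transcripts and equal in 1093, so 1 was added to them and positions are given counted from 1. The table's column for Dnm1l bears the name of its protein, Drp1, and was matched to the sample by that synonym. The table has 0 mitochondrially encoded transcripts, and 1 line without content was not analysed here.

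The depth of each library was estimated because the table gives no counts. In genes with a single transcript of at least 3000 bases, low FPKM values multiplied by length lie near whole multiples of a constant, the worth of 1 fragment. This constant gave 37600000 fragments in control, 35200000 in Dnm1l-/-, 36000000 in Fis1-/- and 35600000 in Mff-/-. In the same order, 91.3%, 94.1%, 90.6% and 93.8% of 427, 457, 436 and 481 such low values lay within 0.15 of a whole multiple. StringTie divides fragments among overlapping transcripts, so single counts were not recovered for most genes and no count model was used. In libraries simulated with counting noise alone, 0 of 10488 genes without a change reached 2-fold in each of the 3 comparisons. Sets of 50 genes were simulated with each size of change. Genes with a 3-fold change were found in 80%, 88% and 94% of cases for Dnm1l-/-, Fis1-/- and Mff-/-, those with a 4-fold change in 100%, 94% and 90%, and those at exactly 2-fold in 2%, 16% and 16%, since the pseudocount pulls low values towards each other. With an assumed spread between libraries added to it (dispersion 0.02), 3, 1 and 0 genes without a change reached 2-fold in the same order. Genes with a 3-fold change were then found in 86%, 82% and 80% of cases, those with a 4-fold change in 96%, 94% and 94%, and those at exactly 2-fold in 10%, 34% and 26%. The real spread between cultures and between library preparations was not measured.

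The value of a gene was the sum of FPKM over its transcripts. Transcripts were joined by symbol, and of 565 transcripts without a symbol 562 were named through their gene identifier. Genes with at least 1 protein-coding RefSeq transcript (20578) were used, and 10688 of them with a mean of 1 FPKM or more over the 4 libraries were compared. Differences were taken on the log2(FPKM + 1) scale, which understates differences of low genes, each knockout minus control, and counted where they reached 2-fold (1 or -1). No significance test was made with 1 library per group. Values in FPKM are given beside the differences.

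Lists of genes were fixed before the data were examined and cover mitochondrial fission, fusion and cristae, mitophagy and autophagy, glycolysis and lactate, the tricarboxylic acid cycle, oxidative phosphorylation complexes, mitochondrial biogenesis, the mitochondrial ribosome, fatty acid oxidation, peroxisomes, the integrated stress response, chaperones, antioxidant defence, hypoxia, cholesterol synthesis, pluripotency, the formative and the 2-cell-like states, neural ectoderm, mesoderm, endoderm, trophoblast, germline and methylation-silenced genes, imprinted genes, fibroblast markers, the cell cycle, p53 targets, apoptosis, immediate-early genes, interferon response, lysosomes, calcium handling, histones, ribosomal proteins and Y-linked genes. Lists of mitochondrially encoded transcripts and of X inactivation transcripts had 0 protein-coding genes in the table and gave no value. The median difference of a list's measured genes was set among the medians of 10000 random lists of the same size drawn from 20 bins of mean expression, as a description of these libraries, and a list stood apart where it lay outside the central 95% of them. Lists with under 5 measured genes got no percentile. Overlaps between knockouts were set beside the number that independent lists would share and beside 100 draws in which the 4 values of each gene were reassigned among the libraries.

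The genes named were chosen by a rule written before the data were examined. It takes the 3 targeted genes, then in each comparison the 8 genes with the largest and the 8 with the smallest difference among measured genes with at least 5 FPKM in 1 of the compared libraries, leaving out predicted genes and clone names, and up to 4 measured genes of each list with the largest absolute difference. For all 3 knockouts together it takes the 8 genes in each direction with the largest smallest difference. Cldn15 was named through this rule in Fis1-/-, while Eif3j2, Uba1y, Uty, Erdr1, the collagen genes Col1a1 and Col1a2 and noncoding transcripts were named after their values were seen. Of the list members that the rule selects, some are not reported here. A list member given in a comparison where the rule did not select it is one that the rule selected in another comparison.

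Alternatives written beforehand were a pseudocount of 0.1 FPKM, no filter on low values, a filter at a mean of 5 FPKM, FPKM rescaled to the same total in each library (TPM), centring on the median, the most abundant transcript in place of the sum, all genes with noncoding ones included, leaving out the 1% most abundant genes before rescaling, and a threshold of 4-fold. After the data had been seen, 6 more were added. The first 3 were the removal of trends on transcript length and GC content by lowess (fraction 0.3) in the 10108 measured genes with a GC value (94.6%), the exclusion of chromosome 8, and random lists matched on length (10 bins) as well as expression (5 bins). A gene can pass the filter on the mean of the 4 libraries through its value in a knockout, so the lists were also taken with all their members and set among random lists of genes at the same level in control (20 bins). The last 2 rescaled each library to the mean total of the 4 libraries, with and without the 1% most abundant genes, because rescaling to TPM raises all values against a fixed filter and pseudocount. GC content was taken from GENCODE M21 transcripts. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and were tested on simulated data.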

Results

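Polyadenylated RNA of mouse embryonic stem cells was sequenced in 4 libraries, 1 from the parental line and 1 from each of 3 knockout lines made in it. The parental line, E14Tg2a, is a male embryonic stem cell line of 129/Ola origin. It was grown on mouse embryonic fibroblast feeders with leukemia inhibitory factor, and all lines were at passages 30 to 35. The knockout lines lack Dnm1l, which encodes the dynamin-like GTPase Drp1 that constricts mitochondria, or Fis1 or Mff, which encode outer membrane proteins that act in mitochondrial fission. The series title states the question as the part these fission genes play in the shape and energy metabolism of mitochondria. The deposited FPKM values came to 623303 in control, 620692 in Dnm1l-/-, 597921 in Fis1-/- and 707746 in Mff-/-. The spacing of low values gave an estimated 37600000, 35200000, 36000000 and 35600000 fragments in the same order. At these depths 1 FPKM on a transcript of 2 kilobases stood for 70.5 to 75.3 fragments. Among 20578 protein-coding genes, 10688 had a mean of at least 1 FPKM over the 4 libraries and were compared. Each group has 1 library and no replicates, so no difference between groups could be set against the spread between cultures. No test was made, and all values compare these libraries only.

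The targeted genes were examined first. Mff, on chromosome 1 from 82724918 to 82752389 (mm10), has 1 transcript among the deposited values, NM_029409. It stood at 28.9 FPKM in control, 29.2 in Dnm1l-/-, 34.7 in Fis1-/- and 11.8 in Mff-/-, 41.0% of control in its own knockout. Fis1, on chromosome 5 up to position 136966234, has 2 transcripts among these values, which differ in their start. The shorter one, NM_025562, which begins at 136962077, was at 89.4 FPKM in control and 19.5 in Fis1-/-. The longer one, NM_001163243, which begins at 136953275, was at 13.6 in control and 36.8 in Fis1-/-. The sum of both Fis1 transcripts was 103 FPKM in control and 56.2 in Fis1-/-, a log2 difference of -0.86, against -2.14 for NM_025562 alone. Cldn15, a tight junction gene next to Fis1 at 136967869 to 136975845, was at 0.926 FPKM in control, 0.308 in Dnm1l-/-, 0.112 in Mff-/- and 22.7 in Fis1-/-. Dnm1l, on chromosome 16 from 16312228 to 16359031, summed over its 5 transcripts to 35.0 FPKM in control, 35.5 in Fis1-/-, 43.3 in Mff-/- and 22.9 in Dnm1l-/-, the lowest of the 4 libraries. In control and Dnm1l-/-, its noncoding transcript NR_075074 was at 10.5 and 3.75 FPKM. The coding transcripts were at 15.1 and 12.8 (NM_001025947), 4.14 and 4.55 (NM_001276341), 3.63 and 1.48 (NM_152816) and 1.63 and 0.303 (NM_001276340). Most of these lower values were not particular to Dnm1l-/-. In Fis1-/- and Mff-/-, NR_075074 was at 6.13 and 5.81 FPKM, NM_152816 at 2.38 and 0.295, and NM_001276340 at 0.511 and 0.160. NM_001276341 was at 5.42 and 18.1 there. Only NM_001025947 was below control in Dnm1l-/- and above it in both other knockouts. A transcript level cannot show loss of protein where a knockout leaves the RNA in place, so these values bear on the labels only as far as the RNA goes.

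**Figure D1:**
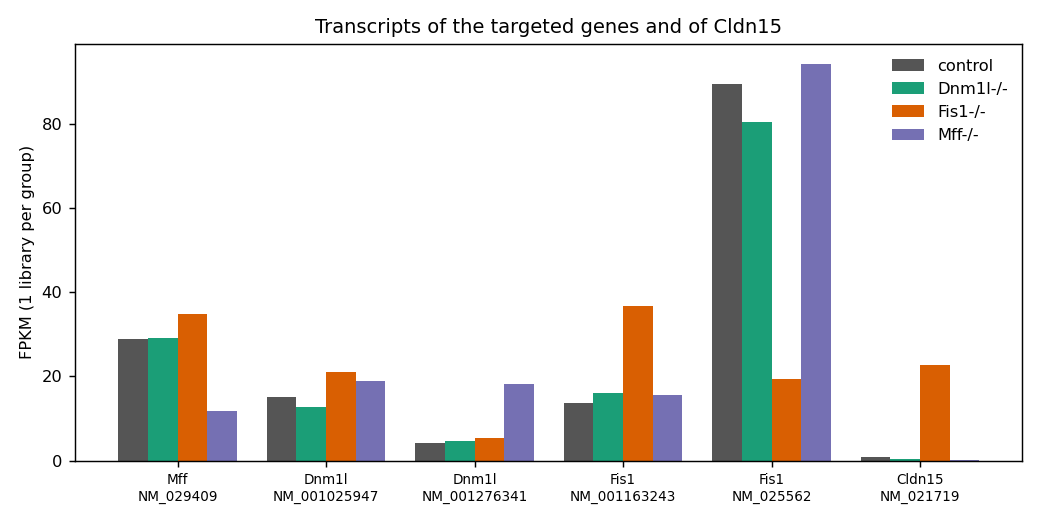
FPKM (vertical axis) of transcripts of Mff, Dnm1l, Fis1 and Cldn15 (horizontal axis) in the 4 libraries, 1 bar per library with no error bar because each group has 1 library. The bar of NM_025562 of Fis1 is at 19.5 in Fis1-/- against 89.4 in control, and Cldn15 is at 22.7 in Fis1-/- alone.

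Dnm1l-/- against control asks what differs in the transcriptome without the fission GTPase. Genes of the 2-cell-like state, a transient state of embryonic stem cells with transcripts of the early embryo, were higher in Dnm1l-/-. Genes silenced by DNA methylation outside the germline were higher as well, and targets of the integrated stress response, the program driven by ATF4, were lower. Zscan4f, a zinc finger gene of the 2-cell embryo, was at 1.3 FPKM in control and 27.3 in Dnm1l-/-, and Rhox5, an X-linked homeobox gene, at 76.8 and 779. Chac1, an ATF4 target that degrades glutathione, was at 31.9 FPKM in control and 2.09 in Dnm1l-/-, and Trib3, a pseudokinase induced by the same factor, at 42.0 and 7.43. Of the 10688 genes, 268 were at least 2-fold higher in Dnm1l-/- and 224 at least 2-fold lower, on the log2(FPKM + 1) scale, and the median over all genes was 0.01.

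By size of the difference, the genes most above control in Dnm1l-/- were Msln, which encodes mesothelin (0.747 FPKM in control and 30.9 in Dnm1l-/-), Zscan4f, C1qtnf9, Zscan4c, Rhox5, Zscan4b, Zscan4d and Serpinb6c (8.20 and 72.6). The genes most below control were Eif2s3y, the Y-linked copy of a translation initiation factor gene (33.0 and 0.136), Eif3j1 (20.1 and 0.0378), the imprinted gene Mest (27.2 and 0.909) and Chac1. They were followed by the lysine catabolism gene Aass (8.78 and 0.423), Crmp1, G0s2, which encodes an inhibitor of triglyceride lipolysis, and the transcription factor gene Tcf15 (40.7 and 6.74). Eif3j1 has a near-identical partner, Eif3j2, which was at 25.3 FPKM in control and 47.6 in Dnm1l-/-, so reads of the pair may have been divided differently and the difference of Eif3j1 is uncertain. The Zscan4 genes and the Rhox genes also share sequence within each family, and values of single members are uncertain for the same reason.

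In the lists fixed beforehand, 8 of 9 measured genes of the 2-cell-like state were at least 2-fold higher in Dnm1l-/- and the median difference was 3.05, above all 10000 random lists of the same size and expression. Of the 25 list members in the table, 9 passed the filter on the mean of the 4 libraries and only 3 were at 1 FPKM or more in control, so the higher values in the knockouts decided in part which members were measured. With the filter left out, 25 of 25 were above control (median 0.89), and this median was at percentile 100 among random lists of genes at the same level in control, an alternative chosen after seeing the data. Of 15 measured germline and methylation-silenced genes, 7 were at least 2-fold higher and 1 lower (median 0.92, percentile 100). Among them were Rhox9 at 4.23 FPKM in control and 36.0 in Dnm1l-/-, Rhox6 at 6.02 and 43.8, and the tubulin gene Tuba3a at 3.0 and 22.6. Of 11 trophoblast genes, 6 were higher and 1 lower by that measure (median 1.18, percentile 100). The keratin genes Krt8 and Krt18 were at 9.73 and 39.9 and at 8.59 and 27.1, and Tead4, a trophectoderm transcription factor gene, at 3.67 and 12.8. In the integrated stress response, 13 of 27 measured genes were at least 2-fold lower and 0 higher (median -0.97, percentile 0), including Atf3 at 11.6 and 2.49 and the mitochondrial gluconeogenic gene Pck2 at 26.8 and 7.92. Genes of the formative and primed state had a median of -0.41 (percentile 0.02), with 1 of 14 at least 2-fold lower. It was the de novo DNA methyltransferase gene Dnmt3a at 7.74 and 2.29, and Dnmt3b was at 31.0 and 17.5. Neural ectoderm genes had a median of -0.49 (percentile 0.31), with 2 of 8 at least 2-fold lower, Sox11 at 2.93 and 0.275 and the neuronal tubulin gene Tubb3 at 69.6 and 23.3.

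Smaller shifts separated 4 further lists from random lists in Dnm1l-/-. Antioxidant defence genes had a median of 0.18 (percentile 99.7), with 2 of 22 at least 2-fold higher. They were the catalase gene Cat at 22.8 FPKM in control and 59.3 in Dnm1l-/- and the stress regulator gene Nfe2l2 at 17.1 and 43.8. Cholesterol synthesis genes had a median of 0.18 (percentile 99.2), with 0 of 23 beyond 2-fold. Interferon response genes had a median of 0.19 (percentile 99.2), with Oasl1 at 4.38 and 39.9 and the transcription factor gene Irf7 at 7.47 and 19.4. Endoderm genes had a median of 0.30 (percentile 98.8), with 0 of 9 beyond 2-fold and laminin genes on both sides of 0, Lama1 at 5.81 and 9.02 and Lamb1 at 8.33 and 4.81. This median was -0.03 when the 1% most abundant genes were left out and each library was rescaled to TPM. In this setting 12422 genes passed the filter. When the libraries were rescaled to their mean total instead, an alternative chosen after seeing the data, the median did not change sign. Pluripotency genes did not stand apart (median 0.05, percentile 79.6), although Tfcp2l1 was at 35.4 and 114, Nanog at 221 and 437, and Dppa3 at 26.2 and 8.20. Differences in Dnm1l-/- were related to GC content across genes (Spearman -0.34, genes not being independent replicates), and the median of chromosome 8 genes less that of other autosomes was -0.32. Without the filter on low values, which adds genes near 0, and against random lists at the same level in control, the median was 0.71 for germline and methylation-silenced genes (percentile 100). It was 0.00 for trophoblast (percentile 47.1, with 9 of 20 above control and 9 below), -0.02 for neural ectoderm (percentile 12.8), -0.04 for endoderm (percentile 16.6) and 0.14 for interferon response (at the edge of the central 95%), so that these 4 lists no longer lay outside the central 95%.

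Fis1-/- against control asks the same of the outer membrane protein Fis1. The stress response, 2-cell-like and methylation-silenced groups stood on the same sides as in Dnm1l-/-. Chac1 was at 1.43 FPKM in Fis1-/- against 31.9 in control, Trib3 at 3.52 against 42.0, Zscan4f at 15.9 against 1.3, and Rhox5 at 764 against 76.8. In Fis1-/-, 192 genes were at least 2-fold higher than control and 202 at least 2-fold lower, with a median over all genes of 0.01. The genes most above control were Msln (22.1 FPKM in Fis1-/-), Cldn15, Rhox5, Zscan4f and Zscan4c, then the testis-expressed X-linked gene Fmr1nb (5.28 in control and 36.5 in Fis1-/-), Zscan4b and Arl14epl (1.3 and 11.6). The genes most below it were Eif2s3y (0.0834 in Fis1-/-), Eif3j1 (0.0369), Chac1, Trib3 and G0s2 (9.89 in control and 0.282 in Fis1-/-). They were followed by Mest (2.61 in Fis1-/-), the glycine transporter gene Slc6a9 (7.85 and 0.660) and the proteoglycan gene Srgn (5.19 and 0.246).

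Among the lists, 15 of 27 genes of the integrated stress response were at least 2-fold lower in Fis1-/- and 0 higher (median -1.17, percentile 0). Pck2 was at 26.8 FPKM in control and 4.8 in Fis1-/-, and Nupr1, a stress-induced chromatin factor gene, at 80.4 and 17.6. Of the 9 genes of the 2-cell-like state 8 were at least 2-fold higher (median 2.32, percentile 100), and without the filter on low values 25 of 25 were above control (median 0.64, percentile 100 among random lists at the same level in control). Of 15 germline and methylation-silenced genes 6 were higher and 1 lower (median 0.73, percentile 100), Rhox9 at 4.23 and 24.5 among them. Trophoblast genes had a median of 0.38 (percentile 99.9), with 1 of 11 at least 2-fold higher, the helix-loop-helix gene Id2 at 7.46 and 19.2, and Krt19 at 6.07 and 12.7, but with all 20 members the median was 0.06 (percentile 93.7 among lists at the same level in control). Antioxidant defence genes had a median of 0.30 (percentile 100), with Cat at 22.8 and 48.5, Nfe2l2 at 17.1 and 35.4, and the heme oxygenase gene Hmox1 at 93.8 and 58.7. Chaperones and the unfolded protein response had a median of 0.25 (percentile 99.97), with the endoplasmic reticulum chaperone gene Hsp90b1 at 208 and 305 and Pdia4 at 41.7 and 68.4. In the same list Herpud1, a gene of protein degradation at the endoplasmic reticulum, was at 34.6 and 6.81. The p53 targets had a median of -0.25 (percentile 0.19), with Gdf15 at 6.38 and 1.27 and Sesn2 at 65.7 and 28.6, both also members of the stress response list. Endoderm genes had a median of -0.36 (percentile 0.48), with 0 of 9 beyond 2-fold and the collagen genes Col4a1 at 6.08 and 3.83 and Col4a2 at 3.66 and 2.32.

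Nuclear genes of oxidative phosphorylation complex I had a median of -0.14 in Fis1-/- (percentile 1.34), with 0 of 36 beyond 2-fold, Ndufb7 at 209 FPKM in control and 134 in Fis1-/- and Ndufa9 at 119 and 83.5. Cell cycle genes had a median of 0.11 (percentile 99.0), with Top2a, the topoisomerase gene of dividing cells, at 78.6 and 160 and the cyclin gene Ccnd1 at 24.1 and 11.2. Against random lists matched on transcript length as well as expression, an alternative chosen after seeing the data, the percentile was 7.60 for complex I and 92.3 for the cell cycle. Among lists at the same level in control it was 3.74 for complex I. Differences in Fis1-/- were related across genes to GC content (Spearman -0.40) and to transcript length (Spearman 0.15).

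Mff-/- against control asks the same of the receptor Mff. Glycolysis, hypoxia, lysosome and autophagy genes were lower in Mff-/-, and genes of the mitochondrial ribosome were higher, as were markers of fibroblasts, the feeder cells (median 0.40, percentile 99.9). Nuclear genes of oxidative phosphorylation complexes I and V stood above random lists matched on expression, and those of complexes II to IV did not (percentile 95.7). None of these complexes stood apart from lists matched on transcript length as well (percentiles 61.2 for complex I, 70.0 for complexes II to IV and 90.6 for complex V). Eno1, which encodes the glycolytic enzyme enolase, was at 1705 FPKM in control and 693 in Mff-/-, and Ldhb, a lactate dehydrogenase gene, at 712 and 149. Mrps12, a gene of the small subunit of the mitochondrial ribosome, was at 36.7 and 113, and the cytochrome c gene Cycs at 34.0 and 71.5. In Mff-/-, 279 genes were at least 2-fold higher than control and 309 at least 2-fold lower, so that 47.4% of them were higher. The all-gene median was -0.07 with the deposited values. Rescaling each library to the same FPKM total (TPM) moved it by -0.16 and gave 191 higher and 700 lower genes (21.4% higher), of which 176 and 309 were among those of the deposited values. TPM values are larger than FPKM here, so more genes passed the same filter (11370) and the pseudocount weighed less. Rescaling to the mean total of the 4 libraries, chosen after seeing the data, keeps both near the FPKM scale (10697 genes), moved the median by -0.15 and gave 153 higher and 520 lower genes (22.7% higher). Leaving out the 1% most abundant genes before rescaling to TPM moved the median by -0.16 and gave 315 and 1024 of 12422 genes (23.5% higher), or 156 and 485 of 10488 when rescaled to their mean total, and centring on the median gave 345 and 233 (59.7% higher). Percentiles among random lists of the same library are relative to that shift.

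The genes most above control in Mff-/- were the calmodulin-like gene Calml4 (3.38 FPKM in control and 44.2 in Mff-/-), the growth arrest gene Gadd45g (0.907 and 14.5), the calcium-binding protein gene S100a4 (6.70 and 44.0) and Hopx (2.84 and 17.6). They were followed by Zscan4f (9.28 in Mff-/-), Urah (9.78 and 46.6), the glutathione peroxidase gene Gpx2 (1.80 and 10.7) and the acute phase gene Saa3 (1.56 and 9.62). The genes most below control were the protease inhibitor gene A2m (14.2 and 0.613), the phosphoglucomutase gene Pgm2 (74.4 and 10.7), the ERK phosphatase gene Dusp5 (13.4 and 1.94) and Ldhb, followed by the NMDA receptor gene Grin1 (9.23 and 1.3), the glycogen branching enzyme gene Gbe1 (7.57 and 1.07), Patl2 and Rest, which encodes a repressor of neuronal genes (15.6 and 3.22). Differences in this library were related to transcript length, as described below, and these values are not adjusted for it. With length and GC trends removed, 148 of 10108 genes were at least 2-fold higher in Mff-/- and 225 lower.

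Of 24 glycolysis and lactate genes, 18 were below control in Mff-/- and 2 at least 2-fold lower (median -0.41, percentile 0), with the phosphoglucose isomerase gene Gpi1 at 395 FPKM in control and 204 in Mff-/- and the phosphofructokinase gene Pfkl at 179 and 98.0. Hypoxia response genes had a median of -0.61 (percentile 0), with 4 of 16 at least 2-fold lower, among them the prolyl hydroxylase subunit genes P4ha1 at 10.5 and 4.20 and P4ha2 at 12.4 and 4.82. With the length and GC trends removed, the median was -0.28 for glycolysis and for hypoxia, with the same middle gene, so these lists share members and are not independent. Among length-matched lists the percentiles were 0.03 for glycolysis and 0 for hypoxia. Mitophagy and autophagy genes had a median of -0.35 (percentile 0.11), with 4 of 23 at least 2-fold lower, including the mitophagy receptor genes Optn at 7.82 and 2.52 and Bnip3 at 122 and 57.1, and 1 higher, the autophagy receptor gene Calcoco2 at 6.88 and 15.1. Lysosome genes had a median of -0.32 (percentile 0.04), with 3 of 26 at least 2-fold lower, namely the cathepsin gene Ctsl at 171 and 77.2, Glb1 at 40.8 and 18.2 and Lamp2 at 19.9 and 8.69. The tricarboxylic acid cycle and pyruvate entry list had a median of -0.13 (percentile 2.12), with the pyruvate carboxylase gene Pcx at 23.9 and 5.44 and the isocitrate dehydrogenase gene Idh2 at 128 and 53.8.

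Nuclear genes of complex I had a median of 0.46 in Mff-/- (percentile 99.6), with 31 of 36 above control and 0 beyond 2-fold. Those of complex V had a median of 0.62 (percentile 98.8) with 3 of 17 at least 2-fold higher, and those of complexes II to IV a median of 0.46 (percentile 95.7) with 2 of 26. Ndufb10 of complex I was at 112 FPKM in control and 217 in Mff-/-, the ATP synthase genes Usmg5 and Atp5g1 were at 271 and 661 and at 211 and 506, and Uqcr10 of complex III at 295 and 658. Mitochondrial ribosome genes had a median of 0.53 (percentile 100), with 37 of 40 above control and 5 at least 2-fold higher, Mrps16 at 119 and 261 and Mrpl12 at 124 and 260. Differences in Mff-/- were related to transcript length across all genes (Spearman -0.46), with a median of 0.47 in the shortest of 10 length bins and -0.36 in the longest. The median transcript length was 646 bases in the complex I list. Against random lists matched on length and expression the percentile was 61.2 for complex I, 70.0 for complexes II to IV, 90.6 for complex V and 97.9 for the mitochondrial ribosome. With the length and GC trends removed the median of complex I was -0.07.

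**Figure D2:**
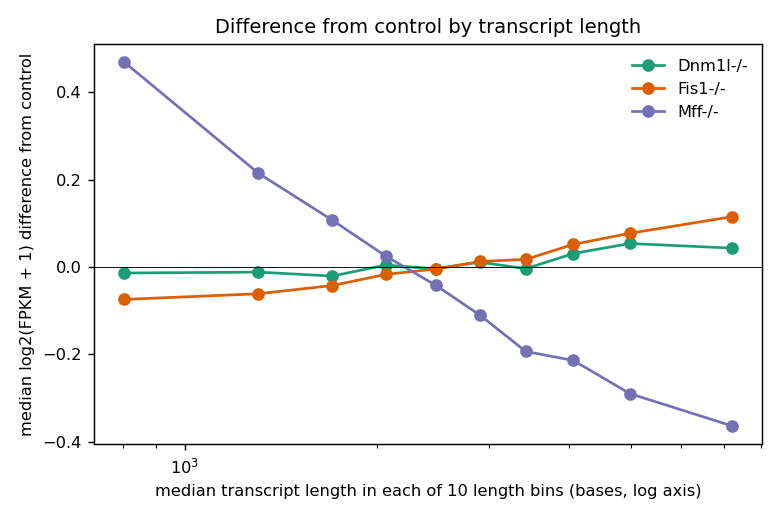
Median log2(FPKM + 1) difference from control (vertical axis) in 10 bins of the 10688 genes by transcript length (horizontal log axis, bases), 1 line per knockout library. In Mff-/- the median is 0.47 in the shortest bin and -0.36 in the longest, and in Dnm1l-/- the corresponding values are -0.01 and 0.04.

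Genes of the 2-cell-like state had a median of 1.10 in Mff-/- (percentile 100), with 5 of 9 at least 2-fold higher, Zscan4f at 1.3 FPKM in control and 9.28 in Mff-/- and Zscan4c at 1.01 and 6.53. Without the filter on low values, 21 of 25 list members were above control and the median was 0.23 (percentile 100 among random lists at the same level in control). Germline and methylation-silenced genes had a median of 0.27 (percentile 99.1), with Rhox5 at 76.8 and 228 and Mael at 2.75 and 7.75. Cholesterol synthesis genes had a median of 0.21 (percentile 98.4), with Pmvk at 31.6 and 68.9. Replication-dependent histone genes had a median of 0.40 (percentile 99.99), with 0 of 18 beyond 2-fold and Hist1h2bc at 10.8 and 20.5. Endoderm genes had a median of -0.53 (percentile 0.595), with 2 of 9 at least 2-fold lower, Col4a1 at 6.08 and 2.06 and Col4a2 at 3.66 and 1.19. Cell cycle genes had a median of -0.08 (percentile 2.05), while the cyclin genes Ccnd1, at 24.1 and 51.5, and Ccnd3, at 114 and 216, were above control. Pluripotency genes had a median of 0.01 (percentile 15.2), with Dppa3 at 26.2 and 64.3, Klf2 at 80.9 and 187, Klf5 at 27.8 and 10.4 and Nr5a2 at 18.2 and 5.31. Against length-matched random lists the percentile was 80.3 for the germline list, 57.9 for histones, 4.45 for endoderm, 29.9 for the cell cycle and 2.59 for the tricarboxylic acid cycle list, all inside the central 95% of random lists. With all members and lists at the same level in control, the median was -0.12 for endoderm (percentile 3.30) and -0.07 for the cell cycle (percentile 6.11). With the length and GC trends removed, also chosen after seeing the data, the median was -0.20 for histones and 0.00 for the cell cycle.

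Markers of fibroblasts, the feeder cells of these cultures, had a median of 0.40 in Mff-/- (percentile 99.9), against 0.00 in Dnm1l-/- (percentile 43.6) and 0.04 in Fis1-/- (percentile 63.4). Of 30 markers, 16 were measured, 4 of them at least 2-fold higher in Mff-/-. These were S100a4, S100a6 at 62.2 FPKM in control and 251 in Mff-/-, the surface protein gene Thy1 at 4.10 and 11.9, and the smooth muscle actin gene Acta2 at 1.71 and 5.21. The collagen genes Col1a1 and Col1a2, abundant in fibroblasts and named after their values were seen, were at 1.5 and 3.27 and at 1.48 and 2.97, and the fibroblast marker Fstl1 was at 16.1 and 7.65.

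**Figure D3:**
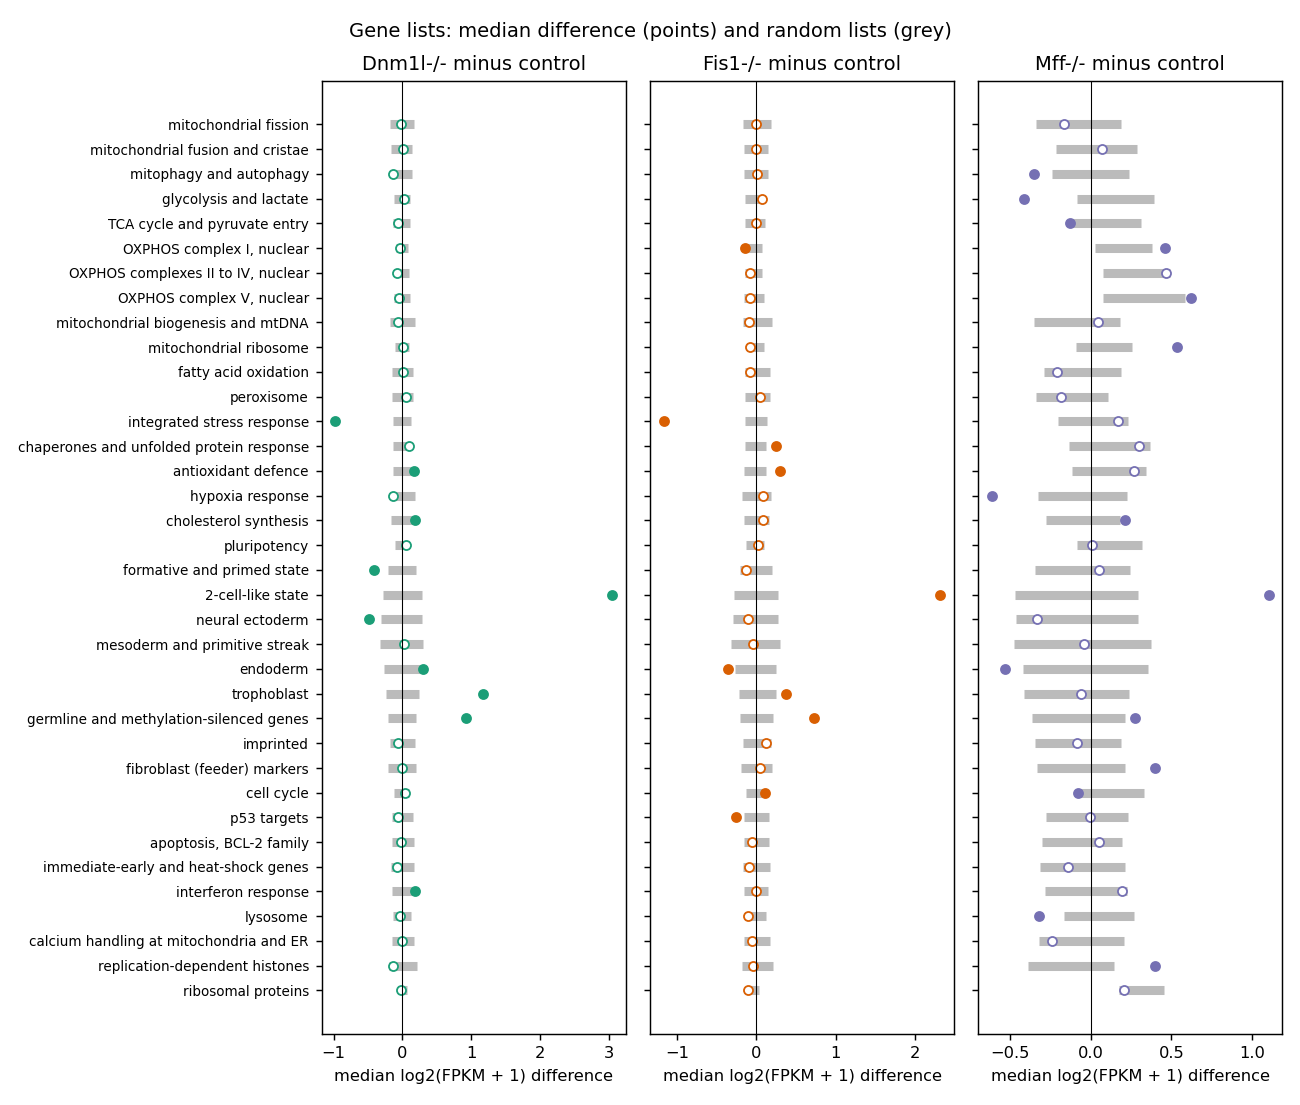
Median log2(FPKM + 1) difference from control (horizontal axis) of each gene list (vertical axis) in Dnm1l-/-, Fis1-/- and Mff-/-, with grey bars spanning the central 95% of the medians of 10000 random lists matched on expression and filled points for lists outside that range. Genes of the 2-cell-like state lie furthest above 0, at 3.05, 2.32 and 1.10, and the integrated stress response lies at -0.97, -1.17 and 0.17.

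Other lists gave the following medians in Dnm1l-/-, Fis1-/- and Mff-/-, in that order, all within the central 95% of random lists matched on expression. Mitochondrial fission genes, with the targeted genes among them, had medians of -0.02, 0.00 and -0.17, and mitochondrial fusion and cristae genes 0.02, -0.01 and 0.07, with Spg7, a mitochondrial protease gene, at 25.9 FPKM in control and 15.5, 16.6 and 16.8. Mitochondrial biogenesis genes had medians of -0.06, -0.09 and 0.04, fatty acid oxidation genes 0.01, -0.08 and -0.21, and peroxisome genes 0.06, 0.05 and -0.18. Imprinted genes had medians of -0.06, 0.12 and -0.08 with members on both sides, Mest at 27.2 FPKM in control, 0.909, 2.61 and 25.1, and Peg10 at 45.5 in control and 138 in Dnm1l-/-. The BCL-2 family and apoptosis list had medians of -0.02, -0.06 and 0.05, with Bmf, a gene of a death-promoting member, at 3.85 in control, 0.894 in Dnm1l-/- and 0.642 in Fis1-/-. Immediate-early and heat-shock genes had medians of -0.08, -0.10 and -0.14, with Egr1 at 15.9 in control and 5.12 in Mff-/-, and calcium handling genes 0.00, -0.06 and -0.24. Mesoderm and primitive streak genes had medians of 0.03, -0.04 and -0.04, with the Nodal antagonist gene Lefty1 at 22.8 in control and 8.02 in Dnm1l-/-, and ribosomal protein genes -0.03, -0.11 and 0.21. Against length-matched random lists 3 of the lists within that range did stand apart in Mff-/-, fatty acid oxidation (percentile 2.06), ribosomal proteins (percentile 0.02) and chaperones (percentile 99.4).

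The remaining medians of the lists described for single knockouts lay inside the range of random lists. In Dnm1l-/- the medians were 0.02 for glycolysis, -0.07 for the tricarboxylic acid cycle, -0.03, -0.08 and -0.04 for oxidative phosphorylation complex I, complexes II to IV and complex V, and 0.01 for the mitochondrial ribosome. They were -0.14 for autophagy, -0.13 for hypoxia, -0.03 for lysosomes, 0.10 for chaperones, 0.04 for the cell cycle, -0.07 for p53 targets and -0.14 for histones. In Fis1-/- they were 0.07 for glycolysis, 0.00 for the tricarboxylic acid cycle, -0.08 for complexes II to IV and for complex V, -0.09 for the mitochondrial ribosome, 0.00 for autophagy, 0.08 for hypoxia and -0.10 for lysosomes. For the other lists they were 0.09 for cholesterol synthesis, 0.02 for pluripotency, -0.13 for the formative state, -0.10 for neural ectoderm, -0.01 for interferon response and -0.04 for histones. In Mff-/- they were 0.17 for the integrated stress response, 0.30 for chaperones, 0.27 for antioxidant defence, 0.05 for the formative state, -0.34 for neural ectoderm, -0.06 for trophoblast, 0.00 for p53 targets and 0.20 for interferon response. With all members and random lists at the same level in control, 4 lists inside that range did stand higher in Mff-/-, complexes II to IV (median 0.46, percentile 98.7), the formative state (0.45, percentile 99.99), mesoderm (0.06, percentile 97.8) and trophoblast (0.08, percentile 98.9). Among genes of these lists, Ldhb was at 240 FPKM in Dnm1l-/- and 388 in Fis1-/- against 712 in control, Calcoco2 at 39.8 and 15.4 against 6.88, and the ATP synthase gene Atp5e at 271 and 275 against 612. In the integrated stress response list, Nupr1 was at 213 FPKM and Pck2 at 61.4 in Mff-/-, against 80.4 and 26.8 in control, while Sesn2 was at 31.7 and Atf3 at 6.19, against 65.7 and 11.6. Of the 36 lists with at least 5 measured genes, 10 stood apart in Dnm1l-/- (7 higher and 3 lower), 10 in Fis1-/- (6 and 4) and 15 in Mff-/- (8 and 7). If the lists were random draws of unrelated genes, 1.8 per knockout would lie outside the range. Genes of a list can vary together and some lists share members. The number of lists outside the range between replicate cultures was not measured, so these counts cannot be set against it.

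The knockouts were then compared with each other. Dnm1l-/- and Fis1-/- were at least 2-fold apart in 36 genes, 23 of them higher in Dnm1l-/-, whereas 1322 genes separated Dnm1l-/- from Mff-/- and 1377 separated Fis1-/- from Mff-/-. With length and GC trends removed, chosen after seeing the data, 909 of 10108 genes separated Fis1-/- from Mff-/-. Part of the distance of Mff-/- may thus follow its trend on transcript length. The log2 values of Dnm1l-/- and Fis1-/- had a Pearson correlation across genes of 0.993, those of either with control 0.968 and 0.973, and those of either with Mff-/- 0.941. Differences from control were shared by 161 higher and 146 lower genes in Dnm1l-/- and Fis1-/-, where independent lists would share 4.81 and 4.23. Reassigning the 4 values of each gene among the libraries at random, which keeps a shared reference but no pairing of libraries, gave on average 124 higher genes in common (at most 152 in 100 draws) and 120 lower genes (at most 140). The correlation of the differences was 0.89 against 0.50 after reassignment, and their covariance 0.190 against 0.142. Dnm1l-/- and Mff-/- shared 33 higher and 12 lower genes (correlation 0.06, covariance 0.0152, independent lists 7.00 and 6.48). Fis1-/- and Mff-/- shared 29 and 12 (correlation -0.02, covariance -0.00549, independent lists 5.01 and 5.84), and after reassignment the means were 124 and 119 genes for the first pair and 123 and 119 for the second. The single control library could not be split, so part of any sharing may come from it.

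**Figure D4:**
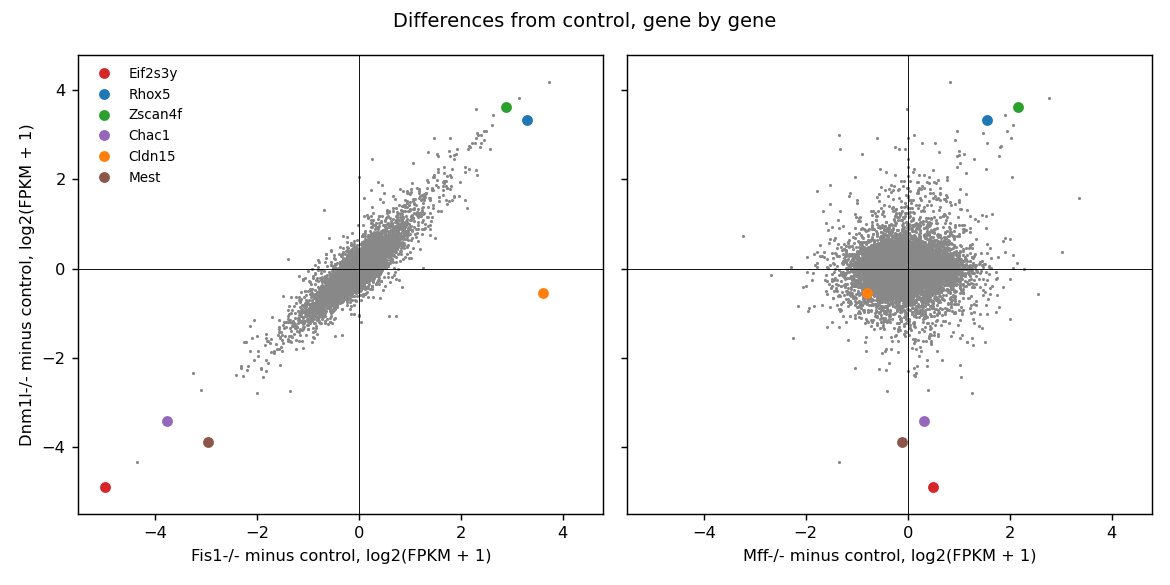
Difference from control, log2(FPKM + 1), of each of the 10688 genes in Dnm1l-/- (vertical axes) against Fis1-/- (left horizontal axis) and Mff-/- (right horizontal axis), 1 point per gene. The differences of Dnm1l-/- follow those of Fis1-/- (correlation 0.89) and not those of Mff-/- (correlation 0.06), and Cldn15 stands out in Fis1-/-.

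In all 3 knockouts, 25 genes were at least 2-fold higher than control and 8 at least 2-fold lower, against 52.9 and 52.6 after random reassignment. With another library in the place of the control, all others were at least 2-fold above it in 6 genes and below it in 14 for Dnm1l-/-, in 2 and 1 for Fis1-/-, and in 181 and 185 for Mff-/-. The genes higher in all 3 with the largest smallest difference were Zscan4f, Zscan4c, the keratin gene Krt17 (10.7 FPKM in control, 81.5 in Dnm1l-/-, 60.3 in Fis1-/- and 33.5 in Mff-/-) and Rhox5, followed by Zscan4d, Calml4, Smpdl3b and Tcstv3, a gene of the 2-cell-like state (0.403, 7.35, 3.08 and 2.01). The genes lower in all 3 were Eif3j1, the transcription factor gene Msc (27.2, 11.2, 9.79 and 9.03), the organic anion transporter gene Slco4a1 and Ndrg2 (32.9, 12.7, 14.9 and 12.4). Next came the peptide hormone gene Apela (103, 40.9, 48.3 and 33.9), the actin-binding protein gene Palld, Srgn and Sesn2 (65.7, 31.3, 28.6 and 31.7). Apela and Palld lie on chromosome 8, where 594 genes were measured and whose median was below that of the other autosomes in each knockout.

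Some differences followed chromosomes. Of 5 Y-linked genes at 1 FPKM or more in control, Eif2s3y, Ddx3y, Uba1y and Uty were below 1% of control in both Dnm1l-/- and Fis1-/-, and all 5 were at 69.8% of control or more in Mff-/-. Ddx3y, a Y-linked RNA helicase gene, was at 3.59 FPKM in control, 0.0121 in Dnm1l-/-, 0.0178 in Fis1-/- and 4.17 in Mff-/-. Erdr1, which lies in the region shared by both sex chromosomes, was at 408, 92.8, 117 and 316. The fixed list of Y-linked genes had 2 measured members, with medians of -3.54 in Dnm1l-/-, -3.57 in Fis1-/- and 0.33 in Mff-/-. On chromosome 8, the median difference from control less that of the other autosomes was -0.32 in Dnm1l-/-, -0.31 in Fis1-/- and -0.28 in Mff-/-, and 83.2%, 82.5% and 76.1% of its genes were below control. The corresponding medians of chromosome 6, which holds Mest, Aass, Ldhb and A2m, were -0.14, -0.15 and -0.17. Leaving out chromosome 8, an alternative chosen after seeing the data, gave 262 higher and 205 lower genes in Dnm1l-/-, 188 and 187 in Fis1-/- and 275 and 273 in Mff-/-.

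**Figure D5:**
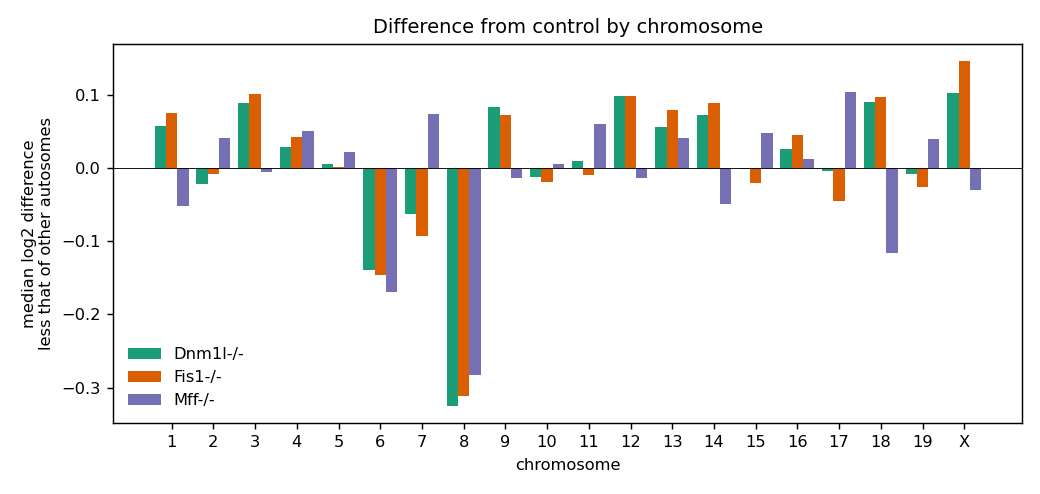
Median log2 difference from control of the genes on each autosome and chromosome X less the median of the other autosomes (vertical axis), by chromosome (horizontal axis), 1 bar per knockout library. Chromosome Y, with 3 measured genes, is not drawn, and of the autosomes and chromosome X, chromosome 8 lies lowest in all 3 libraries, at -0.32, -0.31 and -0.28.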

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

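The tests of the shared control, of a single culture under both labels and of a subclone without a Y chromosome, the separate length tests of oxidative phosphorylation and of the mitochondrial ribosome, and all comparisons with length-matched lists or with trends removed were chosen after the results were seen.

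Some lists stood apart from random lists in opposite directions in different knockouts, and these differences were not tested. The median of complex I genes in Mff-/- lay 0.60 above that in Fis1-/-, and the median of cell cycle genes in Fis1-/- lay 0.19 above that in Mff-/-. The median of endoderm genes in Dnm1l-/- lay 0.66 above that in Fis1-/- and 0.83 above that in Mff-/-. Against length-matched lists complex I and the cell cycle stood apart in neither knockout (percentiles 7.60 and 92.3 in Fis1-/- and 61.2 and 29.9 in Mff-/-), and with trends removed the complex I medians were -0.0031 in Fis1-/- and -0.07 in Mff-/-, so that this gap was gone. The endoderm median in Dnm1l-/- was 0.30 but -0.035 without the filter on low values, where it was -0.15 in Fis1-/- and -0.12 in Mff-/-. In Dnm1l-/- it was -0.034 in TPM without the 1% most abundant genes. It did not change sign there when the libraries were rescaled to their mean total instead. In Mff-/- endoderm was at percentile 4.45 among length-matched lists. The comparisons of protein-coding genes left out noncoding genes. Those with a name and at least 200 bases were screened for higher values only, at least 5 FPKM in a knockout and 4-fold above control on the FPKM + 1 scale. Lower values were not sought. The screen gave H19, an imprinted RNA, at 13.5 FPKM in Fis1-/- against 0.874 in control, and Zscan4a at 12.1 FPKM in Dnm1l-/- against 0.644 in control.

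Nuclear genes of oxidative phosphorylation and of the mitochondrial ribosome were higher in Mff-/-, with a median of 0.52 over 119 genes. The larger FPKM total of that library is argued against as the whole cause, because the median stayed at 0.34 after every library was rescaled to the same FPKM total. The 79 oxidative phosphorylation genes did not stand apart from random lists matched on length (percentile 85.3, with an excess of 0.06 over their median). The trend on transcript length may thus account for these genes, but the comparison cannot show that it does. The 40 mitochondrial ribosome genes were at percentile 97.9 and the pooled list at 98.7, outside the central 95% by a small margin that rests on the ribosome genes. The pooled median exceeded that of length-matched lists by 0.11, so an effect of losing Mff beyond length may remain, as a hypothesis, for the ribosome genes (median 0.25 with trends removed, against 0.03 for oxidative phosphorylation). Differences between cultures or library preparations and a larger share of feeder cells stay open for both groups, since Mff-/- has 1 library in which fibroblast markers were higher too (median 0.40, percentile 99.9 among length-matched lists, with 10 of 16 above control and 6 below). For oxidative phosphorylation the match on length was also incomplete. The shortest genes of the matched lists (median 804 bases in their bin) were longer than the oxidative phosphorylation genes (median 651). The ribosome genes had a median of 1014.5 bases as a whole. The lengths of those inside that bin were not compared, so whether their match was complete is not known.

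Dnm1l-/- and Fis1-/- resembled each other more than either resembled control or Mff-/-. The shared control library is argued against as the whole cause, because the direct comparison of both knockouts, in which control drops out, gave 36 genes at least 2-fold apart, against 1322 between Dnm1l-/- and Mff-/-. The trend of the Mff-/- library on transcript length may be part of the latter number. Between Fis1-/- and Mff-/- the number was 1377, and 909 with length and GC trends removed. A single culture sequenced under both labels is argued against by Cldn15, which differed between the libraries by 4.18 on the log2 scale, and by the main Fis1 transcript (-1.99), and a shared trend on GC content by the correlation of 0.88 that was left after trends were removed. Descent of both lines from a subclone without a Y chromosome and separate losses of it cannot be told apart, because 4 of 5 Y-linked genes were below 1% of control in both lines and either history would leave these values. A common effect of losing the GTPase and Fis1, a history common to both lines, and a difference of culture or library preparation from Mff-/- therefore all stay open. The low stress response medians of these lines share that limit. The 2-cell-like median was high in Mff-/- too (1.10) and is not covered by what Dnm1l-/- and Fis1-/- alone share. All 3 knockouts were compared with the same control library, where only 3 of 25 list members were at 1 FPKM or more. A low level in that 1 library would also give higher medians in all 3 knockouts and cannot be told apart from a common effect.

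Genes of chromosome 8 were lower than control in all 3 knockouts. Trends on length and GC content are argued against, because the smallest shortfall in any knockout was still -0.29 after their removal, and so are a few strongly different genes, because it was -0.26 without genes at least 2-fold apart. Extra copies of chromosome 8 in part of the control cells are a candidate explanation, as a hypothesis, since each of 3 position bins of the chromosome was below the other autosomes in every knockout (-0.21 for the smallest shortfall), and since a gain of this chromosome is a known change of embryonic stem cells in culture. A loss of fission common to all knockouts was not tested as a cause, and DNA of these lines was not analysed here. If the control differs in this way, comparisons of chromosome 8 genes such as Apela and Palld reflect copy number in part.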

How the results depend on the processing

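The removal of length and GC trends, the exclusion of chromosome 8, rescaling to the mean total, and the lists matched on length or on the level in control were chosen after the data had been seen, and all other settings beforehand. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out in turn. A value was taken to move where a count left 1.5 times the main count in either direction, a log2 value moved by as much as a 1.5-fold change, or a correlation moved by 0.1. A change of sign was counted only for lists that stood apart, targeted genes, named genes at least 2-fold apart from control and correlations beyond 0.1. Of 1574 values of counts, list medians, targeted genes and correlations under these settings 1483 did not move, 86 moved and 5 changed sign by this rule. Of 5635 values of single named genes 100 moved and 0 changed sign by it. Other changes of sign are not in these numbers. The ribosomal protein median in Mff-/-, for example, went from 0.21 to -0.23 with trends removed and was taken as not moved. Centring on the median and leaving out chromosome 8 moved none of these 1574 values. The cause of each shift was not tested, except where fewer or more genes enter by construction, as with the filters, noncoding genes and the 4-fold threshold, and for TPM, whose larger values let 11370 genes pass the filter, or 12422 without the most abundant ones, in place of 10688. Depth was similar in all libraries and limits mainly genes near 1 FPKM, and the missing replicates limit all results.

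With a pseudocount of 0.1 FPKM, which lets low genes pass, 380 genes were at least 2-fold lower in Dnm1l-/- (224 with 1 FPKM), 307 higher and 362 lower in Fis1-/-, and 659 lower in Mff-/-. Dnm1l-/- and Fis1-/- were then apart in 103 genes and shared 259 higher and 260 lower genes, Dnm1l-/- and Mff-/- shared 78 and 40, Fis1-/- and Mff-/- 63 and 29, and all 3 knockouts 59 and 22. The medians of the 2-cell-like list were 4.13, 3.38 and 2.07 in Dnm1l-/-, Fis1-/- and Mff-/-. Without a filter on low values these medians were 0.89, 0.64 and 0.23, and in Dnm1l-/- the trophoblast median was 0.00 and the endoderm median -0.035. With a mean of 5 FPKM required, 143 genes were higher and 131 lower in Dnm1l-/- and 105 higher and 125 lower in Fis1-/-. Under that filter Dnm1l-/- and Fis1-/- were apart in 20 genes and shared 91 higher and 90 lower genes, Dnm1l-/- and Mff-/- were apart in 875 and shared 20 higher genes, Fis1-/- and Mff-/- shared 17 higher genes, all 3 knockouts shared 16, and the 2-cell-like median in Mff-/- was 1.70.

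Rescaling to TPM gave 700 lower genes in Mff-/-, 56 genes apart between Dnm1l-/- and Fis1-/-, and 29, 21 and 14 lower genes shared by Dnm1l-/- and Mff-/-, by Fis1-/- and Mff-/- and by all 3 knockouts. With the most abundant transcript in place of the sum, Fis1 differed by -2.14 in Fis1-/-. With noncoding genes included, Dnm1l-/- and Fis1-/- were apart in 66 genes, Mff-/- shared 24 lower genes with Dnm1l-/- and 24 with Fis1-/-, all 3 knockouts shared 17 lower genes, and the correlation of differences between Fis1-/- and Mff-/- was 0.10.

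Leaving out the 1% most abundant genes before rescaling to TPM gave 507 higher and 452 lower genes in Dnm1l-/-, 373 and 412 in Fis1-/-, and 1024 lower genes in Mff-/-. It put 131 genes apart between Dnm1l-/- and Fis1-/-, 2405 between Dnm1l-/- and Mff-/- and 2493 between Fis1-/- and Mff-/-. The shared higher and lower genes were then 304 and 294 in Dnm1l-/- and Fis1-/-, 60 and 60 in Dnm1l-/- and Mff-/-, 49 and 50 in Fis1-/- and Mff-/-, and 42 and 31 in all 3 knockouts. Under this setting the 2-cell-like median was 2.02 in Dnm1l-/- and 1.62 in Fis1-/-, and the endoderm median in Dnm1l-/- was -0.034. When these libraries were rescaled to the mean of their totals instead, which keeps the filter and pseudocount near the FPKM scale (10488 genes), 278 genes were higher and 210 lower in Dnm1l-/-, 199 and 188 in Fis1-/-, and 156 and 485 in Mff-/-. With the most abundant genes kept, rescaling to the mean total gave 275 and 219 in Dnm1l-/-, 218 and 177 in Fis1-/- and 153 and 520 in Mff-/-. The larger counts in Dnm1l-/- and Fis1-/- under TPM thus came with the looser filter and the smaller weight of the pseudocount, and the excess of lower genes in Mff-/- with the scaling itself.

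At a threshold of 4-fold, 52 genes were higher and 22 lower in Dnm1l-/-, 30 and 19 in Fis1-/-, and 14 and 6 in Mff-/-. The pairs were apart in 3 genes (Dnm1l-/- and Fis1-/-), 144 (Dnm1l-/- and Mff-/-) and 131 (Fis1-/- and Mff-/-), and the shared higher and lower genes numbered 27 and 13, 5 and 0, and 4 and 0 for these pairs and 4 and 0 for all 3 knockouts.

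With the length and GC trends removed, 148 genes were higher in Mff-/-, 909 were apart between Fis1-/- and Mff-/-, 18 higher genes were shared by these 2 knockouts and 15 by all 3. In Mff-/- this setting turned the median of complex I genes to -0.074, of cell cycle genes to 0.0040 and of histone genes to -0.20. Against length-matched lists, 11 lists stood apart in place of 15 in Mff-/-, 8 in place of 10 in Fis1-/- and 10 in Dnm1l-/- under both. Differences in Dnm1l-/- were hardly related to length (Spearman 0.05) and more to GC content (Spearman -0.34). No random lists were matched on GC content, so the unchanged count in Dnm1l-/- does not bear on that trend. With all list members and random lists at the same level in control, trophoblast, neural ectoderm, endoderm and interferon response in Dnm1l-/-, trophoblast and complex I in Fis1-/-, and endoderm and the cell cycle in Mff-/- no longer stood apart, while complexes II to IV, the formative state, mesoderm and trophoblast did so in Mff-/-.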

Other observations

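Noncoding transcripts outside the main comparisons also differed between the lines, and those given here were named after their values were seen. The imprinted RNAs Meg3, Rian and Mirg, which are expressed from the maternal copy of 1 cluster, were lower in Dnm1l-/- and Fis1-/- than in control and Mff-/-. Meg3 was at 59.8 FPKM in control, 11.3 in Dnm1l-/-, 21.9 in Fis1-/- and 62.7 in Mff-/-, Rian at 45.9, 9.24, 16.7 and 41.0, and Mirg at 20.7, 3.52, 5.65 and 17.0. Malat1, an abundant nuclear RNA, was at 50.6 FPKM in control, 59.5 in Dnm1l-/-, 49.9 in Fis1-/- and 15.9 in Mff-/-, and Neat1, the scaffold of paraspeckles, at 18.9, 32.7, 19 and 28.1. Xist, the RNA that coats the inactive X chromosome, was between 0.287 and 0.538 FPKM in the 4 libraries, and its antisense partner Tsix between 6.52 and 7.70.

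Of the 14 measured genes of the formative and primed state, 7 were above control and 7 below it in Mff-/- (median 0.05, percentile 76.5), and the 4 with the largest differences there were above it. With the 3 members that the filter on low values left out, 10 of 17 were above control (median 0.45). Fgf15 was at 2.90 FPKM in control, 1.13 in Dnm1l-/- and 12.4 in Mff-/-, Lef1, a transcription factor gene of WNT signalling, at 1.06, 0.166 and 4.96, and Dnmt3b at 31.0, 17.5 and 62.5. Otx2, a transcription factor gene of the epiblast, was at 9.05 FPKM in control and 17.8 in Mff-/-. Dnmt3a was at 7.74 FPKM in control, 2.29 in Dnm1l-/- and 7.43 in Mff-/-. The imprinted gene Phlda2 was at 59.5 FPKM in control and 13.6 in Fis1-/-, and Grb10, an imprinted growth inhibitor gene, at 7.60 and 21.7.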
